A study of Drosophila melanogaster with 3 samples.

How the data were processed

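IDR-thresholded, pooled and per-replicate peak lists were used, each on the dm6 build, with the dm3 lists as an alternative. Per the labels, the samples are 3 biological replicates of embryos aged 0 to 14 hours that express D with a C-terminal GFP, immunoprecipitated with an anti-GFP antibody from chromatin sheared by sonication, with a stated size range of 200 to 800. Per the deposited file lists, peaks and background regions were called on each replicate and on the 3 replicates together, each against a control alignment, and the IDR-thresholded list was made from these lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The deposited signal value of a peak (column 7) is the authors' own measure of its height against the control, on a scale that is not stated. It was used to rank, filter and describe peaks within a list, and ranks were compared across lists of the same length. The deposited −log10 q values (column 9) stop at 1 highest value per list and were used only to count the regions at that value. The list of replicate 1 had 30000 regions with a median signal value of 28.2, that of replicate 2 35.0 and that of replicate 3 43.2. Read depths were not analysed here, so depth is unknown and no value is corrected for it. The 5047 IDR peaks of dm6 were the 5047 peaks of highest signal in the pooled list, so the pooled signal alone decides which regions enter. They held 5011 distinct intervals, as some intervals carry more than 1 summit. Peaks that 1 replicate lacks can enter through the other replicates.

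The annotation was Ensembl release 115 and the sequence was Release 6 of the Drosophila melanogaster genome, the build of the dm6 lists. Only X, 2L, 2R, 3L, 3R and 4 were used. Start sites are those of all protein-coding transcripts of protein-coding genes. A summit within 500 bp of a start site was put in that class first. Positions elsewhere were classed as coding exon, 5' UTR, 3' UTR (with other exons), intron or intergenic, in that order. Only protein-coding transcripts were used for these classes, so intergenic positions can lie in non-coding genes. A gene's territory ran from 2 kb before its start to 2 kb after its end, and a summit can lie in several territories. Peak calls belong to regions, and a summit in a territory does not show which gene it acts on.

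Random placements put the same number of summits on the same arms 1000 times, so that the smallest two-sided p is 0.0020. Arm shares were set against 1000 draws in proportion to arm length. For the dm3 list, each arm was taken to end at its last pooled-list region. Gene lists were set against 10000 random lists matched in 20 bins of territory length, with a smallest p of 0.00020. The alternative by nearest start site kept this matching and did not match on distance to other start sites. Motifs were counted on either strand within 100 bp of the summit and compared with the same window 1000 bp to each side by the exact McNemar test, and the larger p of the 2 flanks was kept. The highest and lowest quartiles by signal were compared by Fisher's exact test. Benjamini-Hochberg adjustment ran over the 19 lists, the 11 motifs, the 6 arms, the 6 annotation classes and the 12 features compared by height. Intervals are exact (Clopper-Pearson) 95% binomial intervals. All p-values treat peaks or genes as the units and do not measure the spread between the 3 replicates. GC-matched windows were drawn on the same arm over 1 kb from any IDR summit, with the number of G and C in 201 bp within 1 of that of the summit, in 1000 sets. Adjustment for these windows ran over the 11 motifs and 1 added sequence, 12 in all. Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9.

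Gene lists, motifs, tests and alternatives were chosen before the data were examined, apart from those said to be added. Genes named in the text are D and SoxN, the genes nearest to the 20 highest peaks, the 10 genes with most summits, the 4 members of each list with the highest signal values and the unbound members where these are 5 or fewer. Genes outside this rule are said in the text to be chosen after their values were seen. Some genes that this rule names are not reported here. Dl and h were matched to the annotation through current symbols. The alternatives were a stricter peak threshold, other distances and windows, other territories, the dm3 lists, other backgrounds, peaks recovered in all 3 replicates and leaving out each replicate in turn. With a single group, no comparison between groups and no paired analysis was made. On simulated data, all 10 lists of 20 genes with a strongly raised binding rate, 200 of 13945 genes, were called, and 0 of 100 unchanged lists were. Smaller rises and lists of fewer than 20 genes were not simulated, so it is not known whether these would be called. In 4997 random windows the Sox core gave a ratio of 1.01 (exact McNemar p = 1.0), and planting it in 5.10% of them gave 1.39 (p = 4.03e-11). Moving 5% of 1997 random summits to start sites was called in 40 of 40 simulated sets, and 4 of 40 unchanged sets had a p under 0.05.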

Results

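D (Dichaete) is an HMG-domain transcription factor of the SoxB class, expressed in the early embryo and later in the nervous system, midline and hindgut. Its binding was mapped by chromatin immunoprecipitation with sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 0 to 14 hours. The embryos carried a transgene for D fused to green fluorescent protein (GFP), and an anti-GFP antibody was used. There was 1 group of 3 biological replicates and no second condition, so the comparisons are between replicates, between bound and unbound positions of the genome, and between gene groups. The main list held 5047 peaks on the dm6 build that passed the authors' threshold on the irreproducible discovery rate (IDR), here called IDR peaks. Their signal values, the authors' own measure of peak height, ran from 188 to 4534 with a median of 310. Each replicate also had its own list of 30000 peaks and background regions, and the depth of the libraries is unknown.

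The 20 highest IDR peaks lay at promoters, in introns and in intergenic positions, near genes of several kinds. The peak with the highest signal value, 4534, lay on X from 2703659 to 2704103, with its summit 38 bp from a start site of Ugalt, which encodes a UDP-galactose transporter. It ranked 1, 1 and 2 in replicates 1, 2 and 3. The second, at 4420, lay on 2R from 22514072 to 22514527, within px, a wing vein gene, 200 bp from one of its start sites. The third, at 4125, lay on 2L from 480838 to 481337 in an intron of ush, which encodes a cofactor of GATA factors. The start site nearest to this peak belongs to cbt, which encodes a zinc finger factor. A peak of 3107 lay 101 bp from a start site of Chro, a chromodomain protein gene, and one of 2829 lay 460 bp from a start site of ph-p, a Polycomb group gene. A peak of 2812 lay in an intron of Trl, which encodes GAGA factor, and one of 2480 in an intron of HmgZ, a gene of an HMG-box protein. The remaining genes nearest to the 20 highest peaks were CG11050, CG14100, CG13323, hll, CG31668, Art3, CG1888, Lk6, CG32772, Tina-1, PNPase, CG9663 and CG18549. The peaks nearest to CG13323, hll and CG31668 lay outside protein-coding genes, 11956, 2912 and 3743 bp from the start site. Of the peaks named here with signal values, those at Chro and Trl had no summit within 200 bp in the whole list of replicate 1, while they ranked 7 and 10 in replicate 2 and 16 and 11 in replicate 3.

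The D locus held IDR peaks. The gene lies on 3L from 14175610 to 14178620 on the minus strand, and 5 IDR summits fell between 2 kb before and 2 kb after it, a span called its territory below. The highest, with a signal value of 1605, ranked 92 among the IDR peaks. It lay 180 bp from a start site of D, ranked 45 in replicate 2 and 28 in replicate 3, and had no match in replicate 1. A second peak, at 839 and 3125 bp from the nearest start site, lay beyond the 3' end of the gene and was matched in every replicate. Of the 5 summits, 1 was recovered in all 3 replicates by the rule given below. Whether the control carries the same transgene is not given, so an extra copy of the D region is not separated from binding here. SoxN, the SoxB gene that acts redundantly with D in the early nervous system, had no IDR summit in its territory. The nearest summit lay 5341 bp from SoxN, with a signal value of 391, and the highest of the 2 pooled-list peaks within its territory had a signal value of 178, below the threshold.

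**Figure D1:**
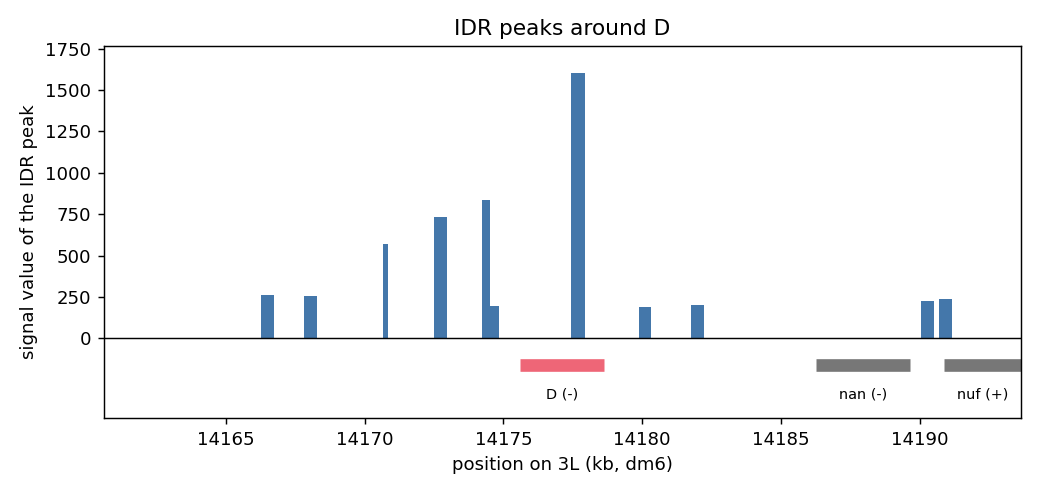
IDR peaks around D on 3L of the dm6 build. Each bar spans a peak interval and its height is the authors' signal value. Genes are drawn below with their strand. The highest bar, 1605, stands inside D near one of its start sites, and 2 summits share its interval.

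The first comparison asked how far the 3 replicates gave the same peaks. For each replicate, an IDR peak was taken as recovered if its summit lay within 200 bp of one of the 5047 highest summits of the replicate's own list. All 3 replicates recovered 1941 peaks, 38.5% of the list (95% exact binomial interval 37.1 to 39.8, which covers the counting of peaks only). No peak list was remade with a replicate left out, so leaving out 1 replicate means here keeping the IDR peaks recovered in both others. Replicates 2 and 3 stood together and replicate 1 apart. Replicate 1 recovered 2524 of the 5047 peaks, replicate 2 recovered 4301 or 85.2% and replicate 3 4236 or 83.9%. Replicates 2 and 3 shared 74.9%, and 1840 peaks, 36.5%, were recovered in replicates 2 and 3 and not in replicate 1. In the highest quartile by signal value, replicate 1 recovered 65.5% and the others 99.8% and 99.7%. In the lowest quartile the values were 33.7%, 57.3% and 55.8%. Spearman's rho of the signal values was taken across IDR peaks with a summit within 200 bp in the whole lists of both replicates. These peaks are not independent replicates. It was 0.71 between replicates 1 and 2 (2783 peaks), 0.68 between 1 and 3 (2765) and 0.79 between 2 and 3 (4907). The mean was 0.727 ± 0.056 (SD of the 3 pairs). The pairs rest on unlike sets, and peaks that replicate 1 lacks do not enter its 2 values. In the list of replicate 1, 819 regions stood at the highest −log10 q value, against 5703 and 5553 in the lists of replicates 2 and 3.

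**Figure D2:**
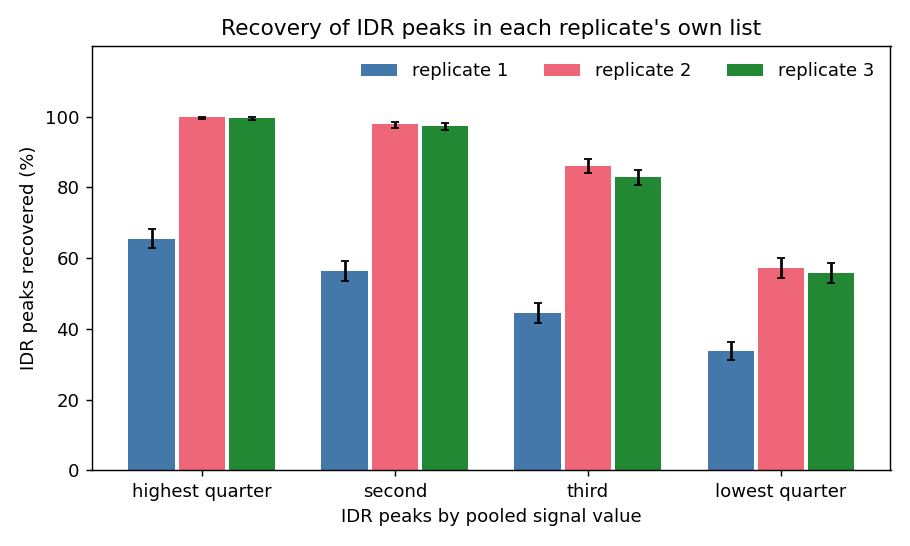
Share of IDR peaks recovered in each replicate's own list (%), by quartile of the pooled signal value. Bars are shares within a quartile and error bars are 95% exact binomial intervals. Replicates 2 and 3 reach 99.8% and 99.7% in the highest quartile, and replicate 1 reaches 65.5%.

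The second comparison asked where the summits lie relative to genes. Start sites of protein-coding genes were bound far more often, and coding exons far less often, than random positions. Of the 5047 summits, 1754 or 34.8% lay within 500 bp of a start site (interval 33.4 to 36.1), against 11.5% of random placements on the same arms (permutation p = 0.0020, two-sided, the smallest the placements can give). Among 22054 pooled-list summits below the threshold and over 1 kb from any IDR summit the share was 18.2%. Coding exons held 8 summits, 0.16%, against 14.0% at random, and 3' UTRs 0.77% against 4.53% (both permutation p = 0.0020). Introns held 41.0% against 39.2% (permutation p = 0.00999) and intergenic positions 22.8% against 30.2% (permutation p = 0.0020). The 5' UTR beyond 500 bp held 0.53% against 0.61%, which did not pass the test (permutation p = 0.579). The sequence at summits was poor in G and C. The median GC content of the 201 bp around a summit was 34.3%, against 41.8% in windows 1000 bp to either side. Against windows of the same GC content, a comparison added after the data were seen, start sites stood at 34.8% against 9.99% and coding exons at 0.16% against 4.95%. The intron share lay below these windows, 41.0% against 44.0%, the opposite direction to that against random placements.

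**Figure D3:**
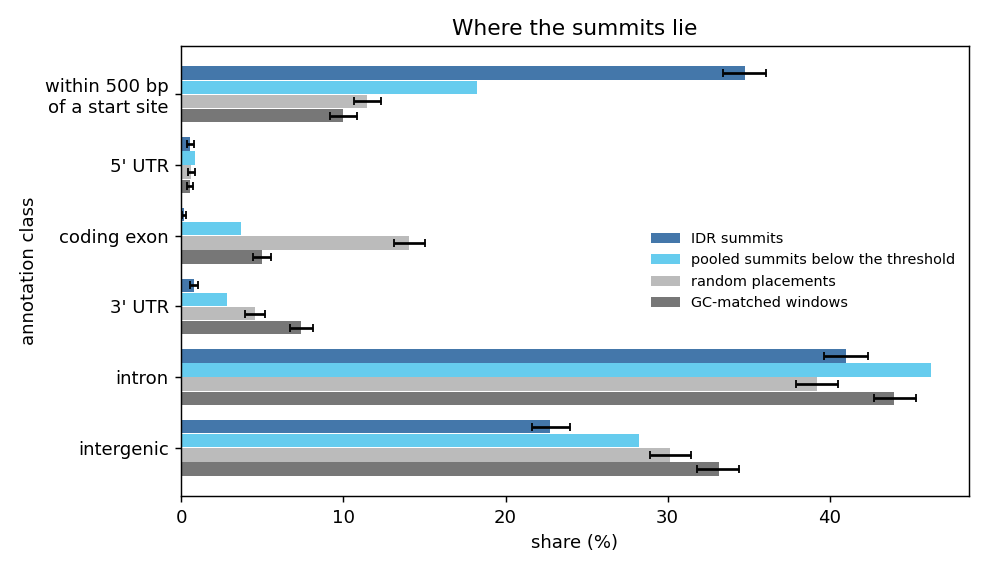
Share of positions in each annotation class (%) for IDR summits, pooled summits below the threshold, random placements and GC-matched windows. The pooled summits are those over 1 kb from any IDR summit. Error bars are 95% exact binomial intervals for IDR summits and 95% ranges of the random sets. IDR summits stand at 34.8% near start sites and at 0.16% in coding exons.

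Summits lay in groups. Of all summits, 58.4% had another within 5 kb, against 31.6% of random placements (permutation p = 0.0020). The gene with most summits in its territory was kirre, a gene of myoblast fusion, with 23 over 398149 bp on X. It was followed by sbb, CG1677 and tara with 16 each. The territory of tara was the shortest of the 10 genes with most summits, at 38679 bp. There were 14 each at px, at shn, which acts in Dpp signalling, at rdx and at jing, 13 at sick and 12 at fz, a Wnt receptor gene, a count that pnt of the glial list below also reached. These counts fell where recovery in the replicates was required. Among summits recovered in both replicates 2 and 3, sbb had 15, CG1677 14, kirre 14, jing 12, rdx 12, tara 12, px 11, sick 10, shn 9 and fz 8. With recovery in replicates 1 and 3, kirre had 13, CG1677 10, sbb 9, fz 8, px 7, sick 7, shn 5, rdx 4, jing 3 and tara 0. With recovery in replicates 1 and 2, kirre had 14, CG1677 11, sbb 10, px 9, fz 8, shn 8, sick 8, rdx 4, jing 3 and tara 0. Counted by nearest start site, kirre had 9 summits, fz 2 and CG1677 1. Of 96 genes singled out by the naming rule that had a summit in their territory, 28 had none among peaks recovered in all 3 replicates. With these 28 included, 57 had fewer summits there by over 1.5 times. Among 13945 protein-coding genes, 4239 or 30.4% had at least 1 summit in their territory, 157 had 5 or more and 22 had 10 or more. Higher peaks lay at promoters more often. Start sites were within 500 bp in 44.7% of the highest quartile by signal value and in 28.1% of the lowest (Fisher's exact test, odds ratio 2.07, p = 4.03e-18). Among peaks recovered in all 3 replicates the odds ratio was 5.44.

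Over the chromosome arms, 3L and 2L held more summits than their share of the length, with 41.5 and 41.0 summits per Mb against 37.5 on X. Arm 2R held fewer, 16.5% against 18.9%, and so did chromosome 4, with 18 summits or 0.36% against 1.01% (adjusted permutation p of 0.0040 to 0.0060 for these 4 arms). Expected shares used whole arm lengths. Limiting each arm to its span of summits, done for X only, moved the expected share of X from 17.6% to 19.5%. The calls of these 4 arms may also depend on this choice. X held 17.5% against 17.6% and did not pass the test (permutation p = 0.883), nor did 3R. These 4 arms were also set, without a test, against pooled-list summits below the threshold and over 1 kb from any IDR summit. There 2L stood in the opposite direction, 19.1% against 19.6%, while 3L stood higher, 23.1% against 22.2%. Arms 2R and 4 stood lower, 16.5% against 17.4% and 0.36% against 1.13%. Among peaks recovered in all 3 replicates, X held 19.5%, above its share of length (permutation p = 0.036). On the dm3 build, with each arm taken to end at its last pooled-list region, X lay below expectation, 17.5% against 18.7% (permutation p = 0.030). X also lay below it against the span of summits on each arm, added after the data were seen, 17.5% against 19.5% (permutation p = 0.0020).

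The third comparison asked which groups of genes were bound, using 19 gene lists. The number of members with a summit in their territory was set against 10000 random lists matched on territory length, with Benjamini-Hochberg adjustment over the lists. Genes of ribosomal proteins stood far above their matched lists. Of 85, 69 were bound, against a mean of 18.0 in matched lists (adjusted permutation p = 0.0019). Among them, RpS27 had a peak with a signal value of 1249 and RpL7 one of 928. In 62 of the 85 genes a summit lay within 500 bp of the gene's own start site. These peaks were largely those of replicates 2 and 3. In a comparison added after the data were seen, 13 of the 70 such summits or 18.6% were recovered in replicate 1, against 39.3% of the other start-site summits (Fisher's exact test, odds ratio 0.35, p = 0.00038). Among peaks recovered in all 3 replicates, 10 of the 85 genes were bound and the call was lost (ratio to matched lists 1.88, adjusted permutation p = 0.675). Subunit genes of the proteasome, another set of broadly expressed genes, had 11 of 32 bound against 7.58 (ratio 1.45) and were not called. The highest peaks lay in the territories of Rpn5, Prosalpha3, Prosalpha4 and Rpt6, and each of these genes had 0 summits by gene body and by nearest start site. By nearest start site, 1 of the 32 was bound (ratio 0.23). With recovery in replicates 1 and 3 or 1 and 2, 2 of the 32 were bound, and the ratio of 1.45 became 0.89 in both.

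Genes of the Notch pathway and the E(spl) complex were also bound more often than matched genes, 13 of 21 against 6.75 (adjusted permutation p = 0.025). The highest peaks were at numb, an inhibitor of Notch, with a signal value of 1689, at E(spl)m7-HLH with 1497, at E(spl)m3-HLH with 1483 and at gro, which encodes a corepressor, with 1055. Many of these genes are neighbours on 3R. With 1 member per run of neighbours, 6 were bound and the call was lost (ratio 1.24, adjusted permutation p = 0.817). It was also lost among peaks recovered in all 3 replicates (ratio 1.97, adjusted permutation p = 0.675), by gene body (ratio 1.36, adjusted permutation p = 1.0) and for the upper 50% of peaks (ratio 2.25, adjusted permutation p = 0.052). With recovery in replicates 1 and 3 or 1 and 2, 6 of the 21 were bound. The summits at gro, 3 in the full list, were then 0, and 1 with recovery in replicates 2 and 3.

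No list of genes tied to known sites of D function passed the adjusted threshold by territory in the full list of peaks. Midline and axon guidance genes had 15 of 18 bound against 9.98 (permutation p = 0.0186, adjusted 0.088). The highest were otp with a signal value of 1209, the netrin receptor gene fra with 1088, the EGF ligand gene spi with 911 and NetA with 860. In their territories comm, robo3 and vvl had no IDR summit. The nearest lay 5581, 19984 and 2518 bp from these genes, that of vvl just outside its territory. With recovery in replicates 1 and 3 or 1 and 2, 10 and 9 of the 18 were bound (ratios 1.64 and 1.46), and spi had 0 summits. Matching on the number of start sites in the territory as well as its length, added after the data were seen, gave an adjusted permutation p of 0.035 for this list. Glial genes had 7 of 9 bound against 3.69 (permutation p = 0.0496, adjusted 0.167), with 12 summits at pnt, and peaks at moody, loco and Gli, but gcm and repo, a pair of glial fate regulators, were unbound. With recovery required in replicates 2 and 3, pnt kept 10 summits, loco 3 and Gli 1. With recovery in replicates 1 and 3 or 1 and 2, pnt kept 7 and 6 and loco and Gli 0. In the Sox family 6 of 8 were bound against 3.64, with signal values of 2077 at Sox14, 628 at Sox102F and 457 at Sox100B, and SoxN and Sox15 were the unbound members. Factors of neuroblast identity had 12 of 27 bound against 10.8, led by grh with a signal value of 1072, insc, pros and Dr. This ratio of 1.11 turned below 1 among peaks recovered in replicates 1 and 3 (3 bound, ratio 0.58), in replicates 1 and 2 (0.95) and in replicates 2 and 3 (0.99), and insc had 0 summits in the first 2 of these sets. Hindgut and gut genes had 7 of 13 against 5.77, led by the forkhead genes fkh at 1213 and bin at 1193, with bowl and dpp. Terminal neuronal genes had 6 of 12 against 6.57, led by elav with a signal value of 1762, ChAT, VAChT and nSyb. With recovery in replicates 1 and 3 or 1 and 2, 2 of these 12 were bound (ratios 0.55 and 0.54, against 0.91 in the full list) and elav had 0 summits. By nearest start site, the Sox family was called with 7 of 8 bound (ratio 2.51, adjusted permutation p = 0.0205), as were hindgut and gut genes with 9 of 13 (ratio 2.04, adjusted permutation p = 0.041). The lists for these calls were matched on territory length and not on distance to other start sites.

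No list of patterning or muscle genes passed the threshold by territory in the full list of peaks. Gap and head gap genes had 7 of 16 bound against 6.24, led by slp1, bcd, cad and slp2, and pair-rule genes 4 of 12 against 4.28, which were slp1, ftz-f1, slp2 and opa. With recovery in replicates 1 and 3 or 1 and 2, 2 pair-rule genes were bound (ratios 1.14 and 1.12), and ftz-f1 and opa had 0 summits. Segment polarity genes had 5 of 11 against 5.46, led by fz with a signal value of 1449, nkd with 865, ptc and wg. Hox genes had 6 of 8 against 4.83, with the highest peaks at Abd-B, Antp, pb and lab, and Scr and abd-A were unbound. Dorsoventral patterning genes had 9 of 14 against 5.72 (adjusted permutation p = 0.244), led by ush with 11 summits, brk, Doc2 and sog, and Doc3, pnr, scw, tld and tsg were unbound. This list was called among peaks recovered in replicates 1 and 3 (ratio 2.85, adjusted permutation p = 0.038), in replicates 1 and 2 (ratio 2.81, adjusted permutation p = 0.042) and by nearest start site (9 of 14, ratio 2.09, adjusted permutation p = 0.028). It was not called among those recovered in replicates 2 and 3 (ratio 1.46, adjusted permutation p = 0.636), where ush kept all 11 summits, against 6 in each of the former sets. Mesoderm and muscle regulators had 10 of 14 against 6.73 (adjusted permutation p = 0.244), led by Mef2 with a signal value of 1571, tin, how and if, and ap, bap, lbe and sna were unbound. Contractile and muscle structural genes had 5 of 13 against 6.14, with the highest peaks at Tm1, Zasp52, sls and Act87E. When each summit was given to its nearest start site only, 9 pair-rule genes were bound and the list was called, in the opposite direction to that by territory (ratio 3.01, adjusted permutation p = 0.0025). Calls by nearest start site used lists matched on territory length and not on distance to other start sites. Genes far from other start sites can gather more summits in that count.

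Receptor genes of sensory neurons were bound less often than matched genes. The odorant and gustatory receptor list had 9 of 119 bound against 30.0 in matched lists (adjusted permutation p = 0.0019). The highest peaks were at Or85f, Gr97a, Or88a and Gr32a, with signal values from 497 to 617. Among peaks recovered in all 3 replicates the call was lost (ratio 0.72, adjusted permutation p = 0.792), as it was by gene body, with 0 bound (adjusted permutation p = 0.193). Jonah serine protease genes had 0 of 16 bound against 2.86 and were not called (adjusted permutation p = 0.223). Cuticle protein genes of the Cpr family had 9 of 70 against 15.7 and were not called (adjusted permutation p = 0.167), with the highest peaks at Cpr76Ba, Cpr31A, Cpr65Ay and Cpr73D.

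**Figure D4:**
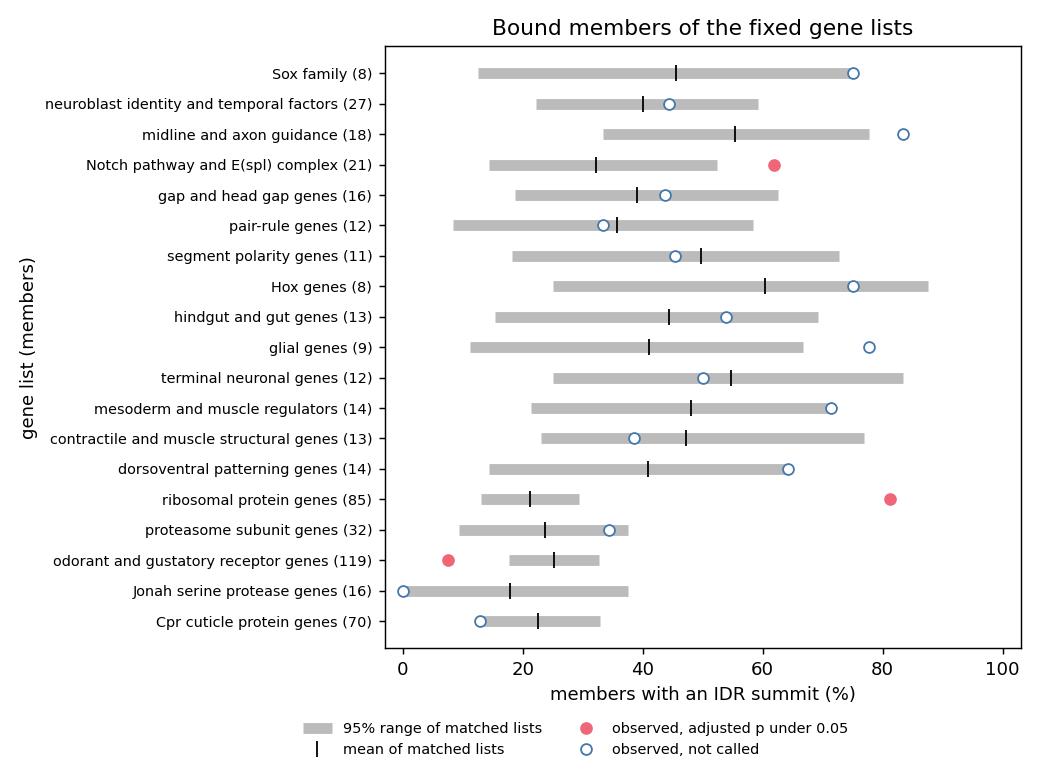
Members with an IDR summit in their territory (%) for the 19 gene lists, with the number of members in brackets. Grey bars are 95% ranges and ticks are means of 10000 length-matched lists. Filled points are lists with an adjusted p under 0.05. Ribosomal protein genes stand at 81.2% against a matched mean of 21.2%, and receptor genes at 7.56% against 25.2%.

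The fourth comparison asked which sequences lie at summits. The Sox core ACAATG was no more frequent at summits than beside them. It was present within 100 bp of 670 summits, 13.3%, and in 12.8% of flanking windows centred 1000 bp away, a ratio of 1.04 (exact McNemar test, p = 0.617, the larger of the values for the 2 flanks). Among the 120 different arrangements of its 6 letters it ranked 75 by this ratio. The A-rich form AACAAT was more frequent at summits than in flanks, 25.7% against 19.7% and 20.4% (ratio 1.28, adjusted exact p = 2.56e-09). This difference was absent against windows of the same GC content, 25.7% against 25.4% (ratio 1.01, permutation p = 0.749). The Sox core stood at 13.3% against 12.5% there (ratio 1.06, permutation p = 0.094). In the highest quartile by signal value the Sox core was less frequent than in the lowest, 10.8% against 16.7% (Fisher's exact test, odds ratio 0.60, p = 1.78e-05). Among peaks recovered in all 3 replicates the odds ratio was 1.13 (Fisher's exact p = 0.616), the opposite direction.

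Sites of other factors were compared in the same way. Against flanks, the homeodomain site TAATTA was present at 18.0% of summits against 12.6% (ratio 1.43, adjusted exact p = 1.37e-12), the GAGA factor site GAGAGA at 11.4% against 8.34% (ratio 1.36, adjusted exact p = 0.00038) and the DREF and BEAF core TATCGA at 9.55% against 7.14% (ratio 1.34, adjusted exact p = 0.00038). Of these, GAGAGA and TATCGA were also more frequent than in GC-matched windows, with ratios of 1.87 and 1.17 (adjusted permutation p = 0.0048 for each), and TAATTA was not, with a ratio of 0.975. The Snail E-box CAGGTG and the Sim and Tango site ACGTG were less frequent at summits than in flanks, with ratios of 0.68 and 0.82, and did not differ from GC-matched windows by the same test, with ratios of 1.01 and 1.02. The proneural E-box CAGCTG had a ratio of 0.82 to flanks (adjusted exact p = 0.058) and of 1.39 to GC-matched windows (adjusted permutation p = 0.0048). The Zelda site CAGGTA, at 3.88% of summits, and the POU octamer, at 3.13%, did not differ from flanks. The octamer and the Caudal site TTTATG lay below GC-matched windows, with ratios of 0.82 and 0.92 (adjusted permutation p of 0.020 and 0.0048). GAGAGA lay more often beside the summit than at it. It was within 25 bp of the summit in 1.84%, and of points 150 bp before and after it in 4.70% and 4.72%. At 1000 bp before and after the summit the values were 2.06% and 2.52%.

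**Figure D5:**
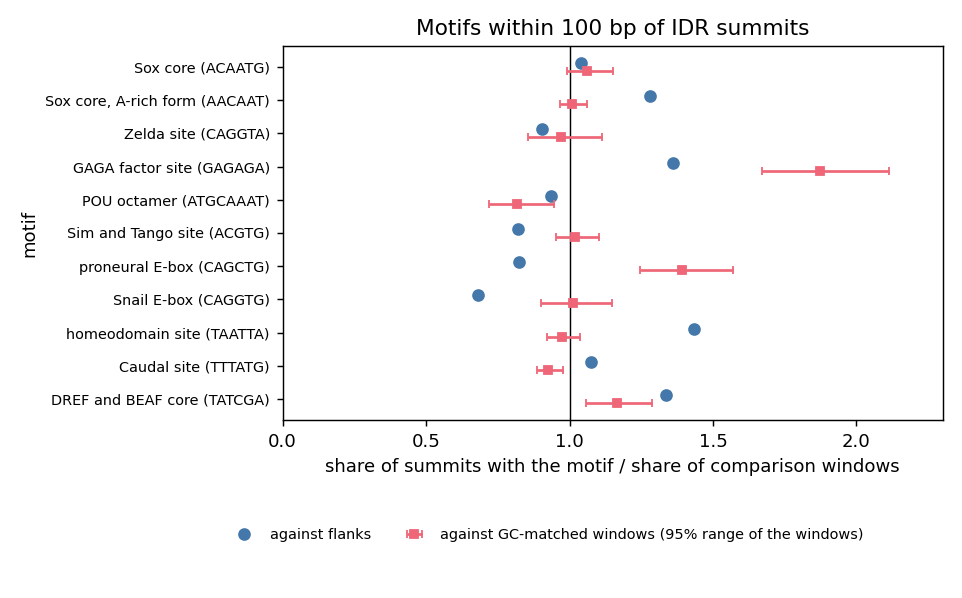
Ratio of the share of IDR summits with each motif to the share of comparison windows with it. Circles are against flanks 1000 bp away and squares against GC-matched windows, with bars for the 95% range of 1000 sets of windows. The Sox core lies at 1.04 and 1.06, and GAGAGA at 1.36 and 1.87.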

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

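The alternatives were chosen before the data were examined, except the added ones: placements or lengths within the span of summits, GC-matched windows, and matching of lists on start sites. Leaving out a replicate kept the IDR peaks recovered in both others, as no list was remade. The share of summits near start sites, its rise with height and the clustering of summits kept their direction and stayed past the threshold under every alternative run. Peaks recovered in all replicates, 38.5%, became 33.7% within 100 bp, 35.7% by interval overlap, 50.6% with lists of 2 times the length, 54.4% with whole lists, 59.3% for the upper 50% of peaks and 36.5% on dm3, and 41.8% to 74.9% when 1 replicate was left out, the highest without replicate 1. Mean rho then ran from 0.681 to 0.790. The share on X, 17.5%, was 17.3% to 19.8% without 1 replicate and 19.5% for peaks of all 3 replicates, past the threshold above the expected share in the latter and without replicate 2 or 3. On dm3, with arms ending at their last pooled-list region (17.5% against 18.7%), and against the added span of summits (17.5% against 19.5%) it passed the threshold below it. The count of lists bound more often, 2, was 1 for the upper 50% of peaks, 0 for peaks of all 3 replicates, 1 to 2 without 1 replicate, 1 by gene body, 1 with 1 member per run and 6 by nearest start site, where pair-rule genes turned to a ratio of 3.01. The count by nearest start site was not matched on distance to other start sites. Leaving out replicate 2 or 3, which requires recovery in replicate 1, ended the calls of ribosomal protein genes (ratios 1.97 and 1.74), of Notch genes (1.87 and 1.84) and of receptor genes (0.69 and 0.68), and brought one for dorsoventral genes (2.85 and 2.81). Leaving out replicate 1 kept these 3 calls (4.44, 2.33 and 0.33). Counting by gene body ended the calls of Notch and receptor genes. The Sox core ratio to flanks, 1.04, was 0.88 to 1.17 for other peaks and windows, none past the threshold, and 1.28 for AACAAT and 1.14 for WWCAAW, both past it. The excess of AACAAT was absent against GC-matched windows (ratio 1.01). WWCAAW was at 90.4% of summits and was not compared with such windows. The odds ratio of the Sox core by height, 0.60, was 0.85 for the upper 50% of peaks, 1.13 for peaks of all 3 replicates, and 0.72 to 0.95 without 1 replicate, and of these subsets only the one without replicate 1 passed the threshold. The cause was not tested for any of these. Subsets hold fewer peaks, which by itself weakens tests, and unknown depth limits what a missing peak in replicate 1 can show.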

Other observations

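All tests in this part were added after the patterns they bear on were seen, and those of the D region, of the GC content of start-site peaks and of transposable elements before their own values were known.

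The peaks that replicate 1 lacks differed from those it shares, past the threshold, in 5 of 13 features. The Sox core was not among these (12.5% and 11.6%, Fisher's exact test, adjusted p = 0.559). They were also lower, with a median signal value of 339 against 437. Of 1522 peaks recovered in replicates 2 and 3 with no summit within 1 kb in the whole list of replicate 1, 48.7% lay within 500 bp of a start site, against 28.7% of the 1941 peaks recovered in all 3 (Fisher's exact test, odds ratio 2.35, adjusted p = 4.29e-32). The DREF and BEAF core TATCGA was at 12.7% of the former and 6.75% of the latter (Fisher's exact test, odds ratio 2.02, adjusted p = 1.04e-08). The sequence CACTGAGA, found by a search of 8-mers, was at 1.97% and 6.44% (Fisher's exact test, odds ratio 0.29, adjusted p = 4.81e-10). Within 4 bins of signal value the odds ratios of these 3 features were 2.85, 2.02 and 0.31, and 4 of the 13 features passed the threshold. The highest such peaks, chosen after their values were seen, were at Chro, near CG13323, in Trl, in Lk6, near Psc, a Polycomb group gene, in cno, in CG12769 and at the promoters of CenG1A and Sox14, with pooled ranks of 6, 7, 11, 14, 21, 29, 31, 35 and 40.

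Gene lists of 3 further groups were added after the highest peaks were seen, leaving out members under the 20 highest peaks. Chromatin regulator genes had 19 of 30 bound against 12.3 in length-matched lists (permutation p = 0.018, adjusted 0.0546 over the 3 lists), after 6 members were left out. With all members it had 25 of 36 against 15.2 (adjusted permutation p = 0.0054), but some of these had been seen among the highest peaks when the list was written. Ecdysone response genes had 11 of 15 against 9.11 (adjusted permutation p = 0.46) and heat shock genes 8 of 17 against 4.53 (adjusted permutation p = 0.159). None passed the threshold without those members.

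Replicate 1 recovered 2524 of the 5047 IDR peaks. Lower depth or enrichment would remove low peaks first. Its recovery did fall with height, from 65.5% of the highest quartile to 33.7% of the lowest. It also had 819 regions at the highest −log10 q value of its list, against 5703 and 5553 for replicates 2 and 3. Yet its whole list of 30000 had no summit within 1 kb of 406 highest-quartile peaks that replicates 2 and 3 recovered. This argues against a loss of low peaks as the whole cause, and leaves lower depth or enrichment open as a part. Replicate 1 missed 34.4% of the highest quartile and replicate 2 recovered 99.8%. Quartiles rest on the pooled signal, so peaks high only in replicates 2 and 3 can enter the highest, which favours these replicates there. GC content of the 201 bp around the summit is argued against too as the whole cause of the promoter-rich misses. Within 5 bins of this GC content and 4 signal bins, the odds ratio of absence from replicate 1 for start-site summits was 2.84 (95% interval 2.44 to 3.30). GC content over whole fragments, which can reach beyond this window, was not tested. The whole lists also differed by arm, which was not tested. Replicate 1 had 13.0% of its regions on X and 0.34% on chromosome 4. Replicates 2 and 3 had 18.0% and 17.7% on X and 1.28% and 1.29% on chromosome 4. A library of other embryos, another stage mix within 0 to 14 hours or a mislabelled sample may each remain and were not tested. The design gives no second group, so no biological explanation was tested.

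CACTGAGA, which is not a Sox site, lay within 100 bp of 213 of the 5047 summits, 4.22%, more often beside the summit than at it (within 25 bp of the summit in 0.53%, and of points 50 bp before and 100 bp after it in 1.13% and 1.35%). In a search of 4419 8-mers on X, 2L and 2R, it led, and on 3L, 3R and 4, which the search left out, it was within 100 bp of 4.31% of summits and in 0.465% of flanks (ratio 9.27, exact McNemar p = 1.13e-17). It was not alone, as all 8-mers tested on those arms passed. Some of these are not shifts of it, such as CACTGTGC (ratio 2.98), CACAGTGG (2.29) and ATATTAAA (2.22, at 7.82% of summits). These 3 were not compared with GC-matched windows. Base composition of the summits is argued against by a ratio of 7.66 to GC-matched windows on 3L, 3R and 4, and transposable elements by 1.41% of these summits lying within 200 bp of one, against 0.60% of the others. A library that is not from the D-tagged line cannot be told apart from one that is. An extra copy of D would raise background regions around the gene, and the 40 kb around D held 13, at percentile 88.8 of all genes. This count left out IDR peaks and all regions within 1 kb of an IDR summit. On 3L from 14160610 to 14193620, around D, there were 12 IDR peaks, which lowers the count there. Whether the control carries the same copy is also not given. What binds this sequence was not tested, nor was any biological explanation.

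Binding at 69 of 85 ribosomal protein genes was weighed against 2 explanations. Gene-dense neighbourhoods are argued against, since lists matched on start sites and length gave a ratio of 3.42. In the full list, equal capture of promoters of broadly expressed genes as the whole cause is argued against by proteasome genes, 11 of 32 by territory (Fisher's exact test, odds ratio 8.23, p = 3.24e-06). By nearest start site, where the difference was not tested, the counts were 62 of 85 and 1 of 32. Among peaks recovered in all 3 replicates the counts were 10 of 85 and 2 of 32 (odds ratio 2.00, Fisher's exact p = 0.508), too few to tell. Since 13 of 70 start-site summits were recovered in replicate 1, the pattern rests on replicates 2 and 3, and a difference in expression level between the sets was not tested and may matter.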
